A study of Bos taurus with 12 samples.

How the data were processed

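Total RNA of cattle growth plate chondrocytes was measured on 12 one-colour microarrays, 6 of the hypertrophic zone (HZ) and 6 of the reserve zone (RZ), in pairs numbered 1 to 6. Per the labels, RNA was extracted with RNA STAT-60, its integrity was examined on a Bioanalyzer, and biotin-labelled cRNA was made with an Ambion MessageAmp II kit. The scanner software, the summary of probes into probe sets and the normalization are not given in the sources used here. Each array belonged to the zone and pair number of its title, and the numbers carry the pairing that the series description mentions.

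The deposited values are linear ratios, with 1 value per probe set and array for 24128 probe sets, 112 of them controls. The scale and centring had to be read from the values. For 21901 probe sets (90.8%) the deposited ratio was the array's scaled signal over the median of that probe set across the 12 arrays. For the other 2227 (9.23%), all dim, the divisor was 1 fixed value. The lowest deposited value was 0.01, reached 49 times, and the highest 43.8. Medians of the ratio over all probe sets were 0.997, 0.934, 1.04, 0.971, 0.970 and 0.988 on HZ-1 to HZ-6 and 0.986, 0.988, 0.978, 1.02, 0.969 and 1.01 on RZ-1 to RZ-6. On the log2 scale these medians spanned 0.15, under the limit of 0.2 set for keeping the authors' normalization, and no further normalization was made.

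Ratios to a median hide the level of a probe set, which the choice of probe sets and the handling of dim signals need. Each array's deposited ratios fell on whole multiples of a step, and the step of a probe set relative to that of the dim probe sets gave its divisor. A divisor was accepted when all values of the probe set lay within 0.01 of a step, plus 3e-07 of the number of steps and at most 0.08, of whole multiples. This gave a signal for all 24128 probe sets, with 0.0669 of a step the largest distance. In 4000 simulated probe sets, 99.85% were solved and 99.975% of those were right. Recovered signals had array medians of 96.7, equal to within 0.035%. The unit of signal rests on the assumption that 1 step is 0.1 signal units, which no source states. It sets how large the added constant of 16 is against the signals, and thereby the size of changes in dim probe sets and the number that pass. With 1 or 64 added instead, the direction turned in 546 and 370 of the probe sets, 0 of them among those that passed. This 0 was largely fixed, since no constant can turn a probe set with the same sign in all 6 pairs. Of the 1494 that passed, 1392 had the same sign in all pairs.

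Tests used log2(signal + 16) of the 24016 probe sets that are not controls. The planned design had assumed intensities, and the recovered signal stood in for them. Gene symbols came from the platform's annotation table. Of these probe sets, 13292 had 1 gene symbol, 86 several and 10638 none and stay unnamed here, and 13263 matched by Entrez identifier to the RefSeq gene table of assembly ARS-UCD2.0, which changed 0 symbols. That table was used only for names and neighbouring genes. In all 9155 genes were named, 2913 of them by more than 1 probe set. A gene was represented by its probe set with the highest mean log2 signal over all arrays, and other probe sets are given where they passed in a listed gene that did not, and for some genes that did.

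The zones were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with the pair as a fixed block and 5 residual degrees of freedom), with Benjamini-Hochberg adjustment over all 24016 probe sets and a threshold of 0.05. Errors of log2 differences are standard errors. Same-numbered arrays deviated together from their zone means, with correlations of 0.124 to 0.447 over the 6 pairs, all above the limit of 0.1, and 5 of 6 HZ arrays were closest to the RZ array of their own number. This was decided before the fits were compared. The pairs split into 2 groups by the step size, called batches here although no label names a batch. Spike-in signals were lower in pairs 1 and 2, but with only a narrow gap to the others. Differences are therefore also given within pairs 1 and 2 and within pairs 3 to 6.

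Gene lists, 38 in number, covered growth plate zones, matrix, signalling, cell cycle, metabolism, stress and other cell types. They were tested with limma's camera (preset correlation 0.01, at least 5 measured genes, Benjamini-Hochberg over the lists), and with camera using an estimated correlation and with fry. A gene counts as having risen or fallen when its adjusted p was under 0.05 over all probe sets, and counts adjusted over the list alone use the members' p-values only. The lists, the tests, the alternative settings and the rule for named genes were fixed before the data were examined. The rule took the 15 genes with the largest rise and the 15 with the largest fall among those past the threshold with the same sign in all 6 pairs, every measured hypertrophic and reserve zone marker, up to 4 members with the smallest adjusted p of each other list, and, for other cell types, the 2 members with the highest level. Symbols that are only locus numbers were left out. It gave 185 genes, of which 121 were described and run under the alternatives; that selection, and further members named to complete a count, were made after their values were seen.

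On simulated data with the real spread and 200 of 24016 probe sets changed, the blocked fit of HZ against RZ called 58% of 100 probe sets changed by log2 1 and 98% of 100 changed by log2 2, and 2.5% of its calls were false. In a simulation of 38 lists over 9155 genes, camera, camera with an estimated correlation and fry each found the raised and the lowered list and called 0 of 35 unchanged lists. Both simulations drew the noise independently for each probe set, while the correlation estimated in the real lists reached 0.693 (ribosomal proteins). They therefore cannot show how often camera at the preset correlation calls an unchanged list of correlated genes. RNA quality was read from the 3′ and 5′ control probe sets of actin, GAPDH and EF1A with an exact sign-flip test over the 6 pairs. After their fry results were seen, the same test was made on the mean difference of the leukocyte gene sets.

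The alternative settings fixed beforehand were no block, a random block, quantile normalization, median centring, added constants of 1 and 64, leaving out the dimmest 25% or 50% of the probe sets, a variance trend with robust moderation, array weights, a paired test without moderation, each pair left out, the mean of a gene's probe sets, an estimated correlation and fry. After the data were seen, the deposited ratio itself, each batch alone, the arrays without pairs 3 and 4, and gene lists without probe sets above a signal of 8000 were added. Recovery and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The number of arrays limits the precision.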

Results

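RNA levels were measured in chondrocytes, the cells that form cartilage, taken from the growth plate of the distal metacarpus of male dairy cattle younger than 10 months. The growth plate is the cartilage layer in which long bones lengthen. Its reserve zone (RZ) holds slowly dividing precursor cells, and its hypertrophic zone (HZ) holds enlarged cells that mineralise their matrix. After a collagenase digestion of 4 hours the cells were parted by density, with the lightest fraction taken as HZ and the heaviest as RZ. Each of the 12 arrays held the RNA of 1 fraction, 6 from HZ and 6 from RZ, in 6 numbered pairs with 1 array of each zone. The labels call the pairs independent but do not say whether each came from a single animal, so the p-values measure the spread between these pairs. The number of arrays limits the precision of every value.

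The zone and the batch of arrays both separated the samples. Correlations of log2 signal between arrays ran from 0.911 to 0.971. The second principal component (18.9% of the variance) placed each HZ array above all RZ arrays, with HZ-2 nearest to them at 2.56. Along the first component (22.8% of the variance), pairs 1 and 2 stood apart from pairs 3 to 6. The same pairs differed in the smallest step between the deposited ratios of dim probe sets, at 0.0237 to 0.0318 on the arrays of pairs 1 and 2 and 0.00884 to 0.0110 on those of pairs 3 to 6. The median deposited ratio of 7 spike-in probe sets differed too, at 0.514 to 0.730 and at 0.766 to 2.02. Both zones were present in both batches.

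**Figure D1:**
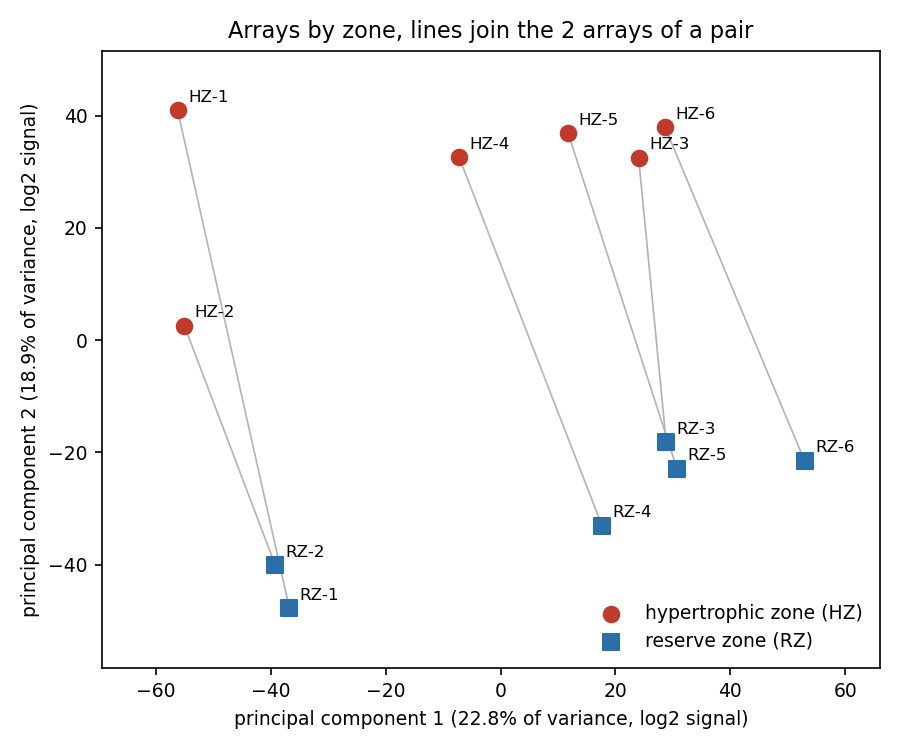
Principal components of the log2 signals, component 1 (22.8% of the variance) on the horizontal and component 2 (18.9%) on the vertical axis, in units of log2 signal, with red circles for HZ, blue squares for RZ and lines joining the arrays of a pair. HZ arrays lie above RZ arrays on the vertical axis, and pairs 1 and 2 lie to the left of the other pairs.

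The comparison of HZ with RZ asked which transcripts differ between terminally enlarging and resting growth plate chondrocytes. In HZ, transcripts of the collagenase MMP13, of the hedgehog ligand IHH and of LOX, which cross-links collagen, rose. Transcripts of the aggrecan-degrading protease ADAMTS4, of the WNT inhibitor SFRP5 and of the microfibril protein FBN1 fell. Mean MMP13 signal was 4728 ± 864 in HZ and 1186 ± 430.5 in RZ (SD, n = 6), a 4.10-fold rise. LOX went from 594 ± 286 to 5484 ± 2279 (SD, n = 6), 9.08-fold, while ADAMTS4 was 3.21-fold lower in HZ and FBN1 2.75-fold lower. Folds were taken on the scale of log2(signal + 16) and understate the change of dim probe sets. In all, 782 probe sets rose and 712 fell out of 24016 (limma with the pair as a block, adjusted p under 0.05), with 364 rising and 249 falling 2-fold or more. Over all 24016 probe sets, 3361 (13.99%) had the same sign in all 6 pairs. Over all ways of swapping the zones within pairs, the average is 3.125%. Since probe sets can vary together, chance can stray from that average, and how far was not determined. Among those that passed the paired test, which favours such probe sets, 1392 had the same sign in all pairs. Probe sets with a single named gene stood for 420 genes that rose and 381 that fell, with CUEDC1 in both counts through different probe sets.

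All 1494 probe sets that passed had the same sign in both batches, which the paired test also favours. Within pairs 3 to 6 alone, 258 probe sets passed as higher and 78 as lower. With pairs 1 and 2 alone, limma passed 0, and 2931 of 24016 had an unadjusted p under 0.05, where chance alone gives a share of about 0.05. A fit of all pairs with a term for the batch, which shares the variance, passed 5 as higher and 13 as lower in pairs 1 and 2, and 301 and 103 in pairs 3 to 6. In that fit, 2 probe sets passed for a difference of the zone effect between batches, that of LOC524810 (-4.36 in pairs 1 and 2, 0.29 in pairs 3 to 6) and an unnamed one (-3.08 and -0.01). An unadjusted p under 0.05 for that term was found in 1207 of 24016, about the share of 0.05 that chance alone gives. Ignoring the pairs left 505 higher and 326 lower. Probes toward the 3′ end over the 5′ end of actin, a sign of RNA degradation or of short labelled copies, gave a log2 ratio of 3.03 ± 0.685 in HZ and 2.34 ± 0.453 in RZ (SD, n = 6), higher in HZ in 5 of 6 pairs (exact sign-flip test, two-sided p = 0.0625, where 0.03125 is the smallest p possible). For GAPDH the log2 ratio was 0.519 ± 0.651 in HZ and 0.103 ± 0.285 in RZ (exact p = 0.125), with 1.47 on HZ-3 and 1.21 on HZ-4. For EF1A it was -2.50 ± 0.394 and -2.26 ± 0.295 (exact p = 0.406). Without pairs 3 and 4, a setting chosen after the data were seen, 91 probe sets passed as higher and 48 as lower.

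Among genes with the same sign in all 6 pairs, the largest rise was that of NT5DC1, a protein with a nucleotidase domain, from a signal of 87.1 ± 26.8 to 1570 ± 617 (SD, n = 6), a log2 difference of 3.87 ± 0.29 (SE, adjusted p = 0.00049). The gene COL10A1 lies inside NT5DC1 on the same chromosome, and each had a single probe set. LOX followed at 3.18 ± 0.27 (SE, adjusted p = 0.000708), then the tight junction protein CLDN6 at 2.67 and the calcium sensor NCALD at 2.63. PYROXD2, the lysosomal acid lipase LIPA, the clock repressor NR1D1, RFTN2, KLHL13 and the small heat shock protein CRYAB rose by log2 2.44 to 2.24. ADM, which encodes the vasodilator peptide adrenomedullin, MPZL2, MMP13, PDE6C and GSK3B, a kinase that acts in WNT signalling, rose by 2.13 to 2.01. For GSK3B, a second probe set rose by 2.18 and another, near the floor, gave 0.20. The second PYROXD2 probe set gave 0.48.

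The largest fall was that of UBD, a ubiquitin-like protein induced by cytokines, at log2 -2.70 ± 0.40 (SE, adjusted p = 0.0075), with -4.11 in pairs 1 and 2 and -1.99 in pairs 3 to 6. NID1, a protein of basement membranes, fell by 1.93, CATHL1, an antimicrobial peptide of granulocytes, by 1.85, and DPEP1 by 1.83. F3, which starts blood clotting, the chemokine receptor CXCR4 and ADAMTS4 fell by 1.81, 1.74 and 1.68. THBS3, NKG7, the serine protease HTRA1 and the gelatinase MMP2 fell by 1.67 to 1.66. TNFAIP6, which binds hyaluronan, MEDAG, ITGA5, a subunit of the fibronectin receptor, and MOB3B fell by 1.62 to 1.58. The other NKG7 probe set gave 0.78 (adjusted p = 0.144), and the other ITGA5 probe sets, both dim, gave -0.03 and 0.25.

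**Figure D2:**
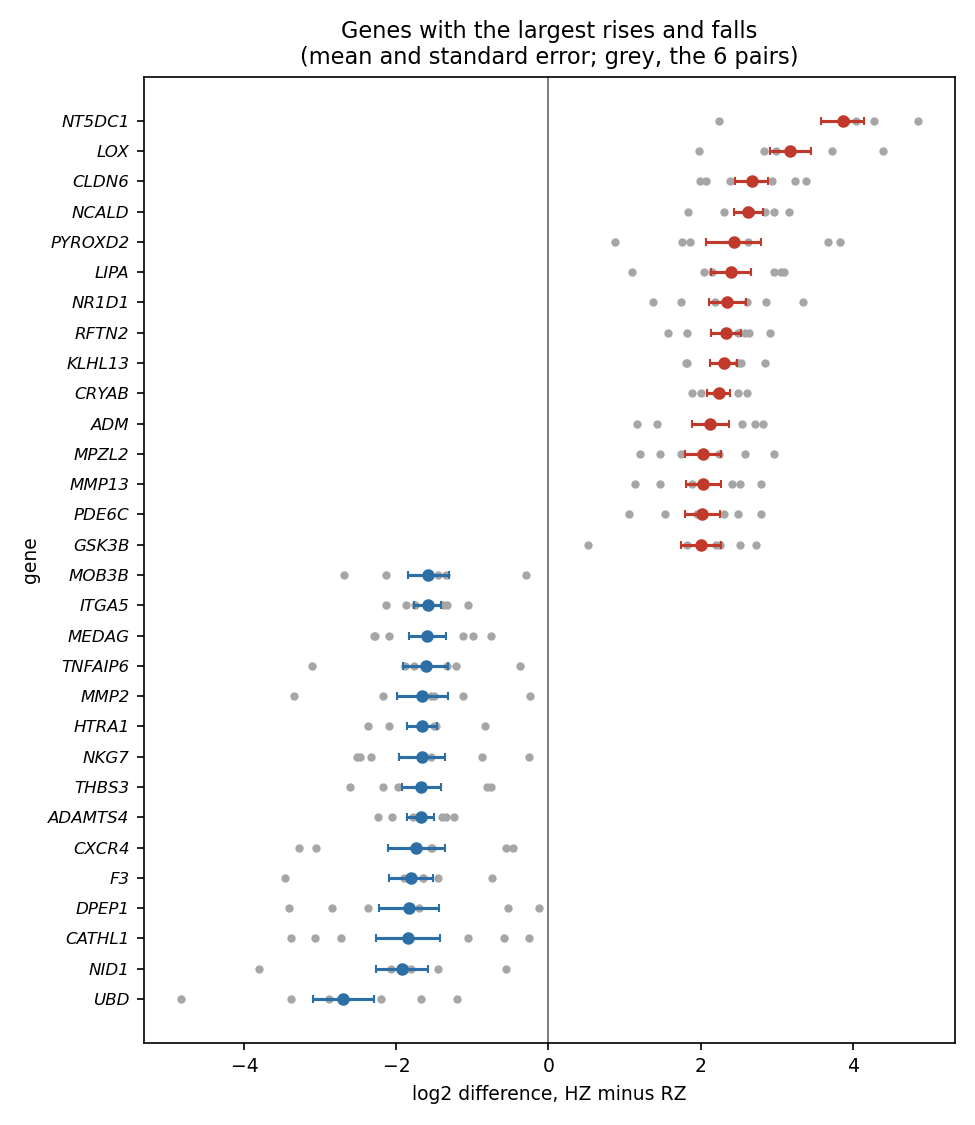
Log2 difference of signal, HZ minus RZ, on the horizontal axis for the 15 genes with the largest rise (red) and the 15 with the largest fall (blue), with the standard error as a bar and the 6 pairs as grey dots. Every grey dot lies on the same side of 0 as its mean.

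Of the 14 measured markers of the hypertrophic zone, 6 rose, 0 fell and 8 did not pass, with 8 rising when adjusted over the list alone. MMP13 rose by log2 2.04 ± 0.23 (SE), IHH by 1.54 ± 0.20, the transcription factor MEF2C by 1.14 ± 0.20 and the parathyroid hormone receptor PTH1R by 0.92 ± 0.15. SCIN, which severs actin filaments, rose by 0.84 and ALPL, the alkaline phosphatase of mineralising cartilage, by 0.73, each in 6 of 6 pairs, although ALPL passed in 1 of 6 fits with a pair left out. The list as a whole rose, with a median of 0.54 (camera adjusted p = 7.76e-07; adjusted p = 0.439 with an estimated correlation), and its median was 0.46 in pairs 1 and 2 and 0.66 in pairs 3 to 6. COL10A1, the collagen that marks hypertrophy, did not pass, at 0.11 ± 0.16 (SE, adjusted p = 0.755), and its sign turned to -0.05 after quantile normalization. Its signal, 21620 ± 4513 in HZ and 20147 ± 4698 in RZ (SD, n = 6), ranked 5 by mean level on these arrays. At the top of the range few probe sets changed, with those of LOXL4 and MGP the 2 of the 100 brightest to pass. IBSP, a bone sialoprotein, gave 0.14 ± 0.17 at its brighter probe set (adjusted p = 0.715), while its other probe set rose by 2.20 ± 0.21 (adjusted p = 0.00125). The log2 difference was 0.31 for SPP1, 0.32 for VEGFA, 0.55 for DLX5, 0.53 for CDKN1C, 0.27 for S100A1 and 0.51 for FGFR1, none of which passed.

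Among the 7 measured reserve zone markers, 4 fell, 1 rose and 2 did not pass, with the same counts when adjusted over the list alone. SFRP5 fell by 1.12 ± 0.16 (SE, adjusted p = 0.00569), the lipoprotein APOE by 0.88, the chaperone clusterin (CLU) by 0.86 and PTHLH, the signal that delays hypertrophy, by 0.75, each in 6 of 6 pairs, although PTHLH passed in 1 of 6 fits with a pair left out. MGP, an inhibitor of mineralisation placed on this list, rose by 0.75 ± 0.15 (adjusted p = 0.0229). GDF5 and the ectonucleotidase NT5E gave 0.19 and 0.29 and did not pass. The list did not pass as a whole, with a median of -0.75 (camera adjusted p = 0.147), -0.89 in pairs 1 and 2 and -0.68 in pairs 3 to 6.

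**Figure D3:**
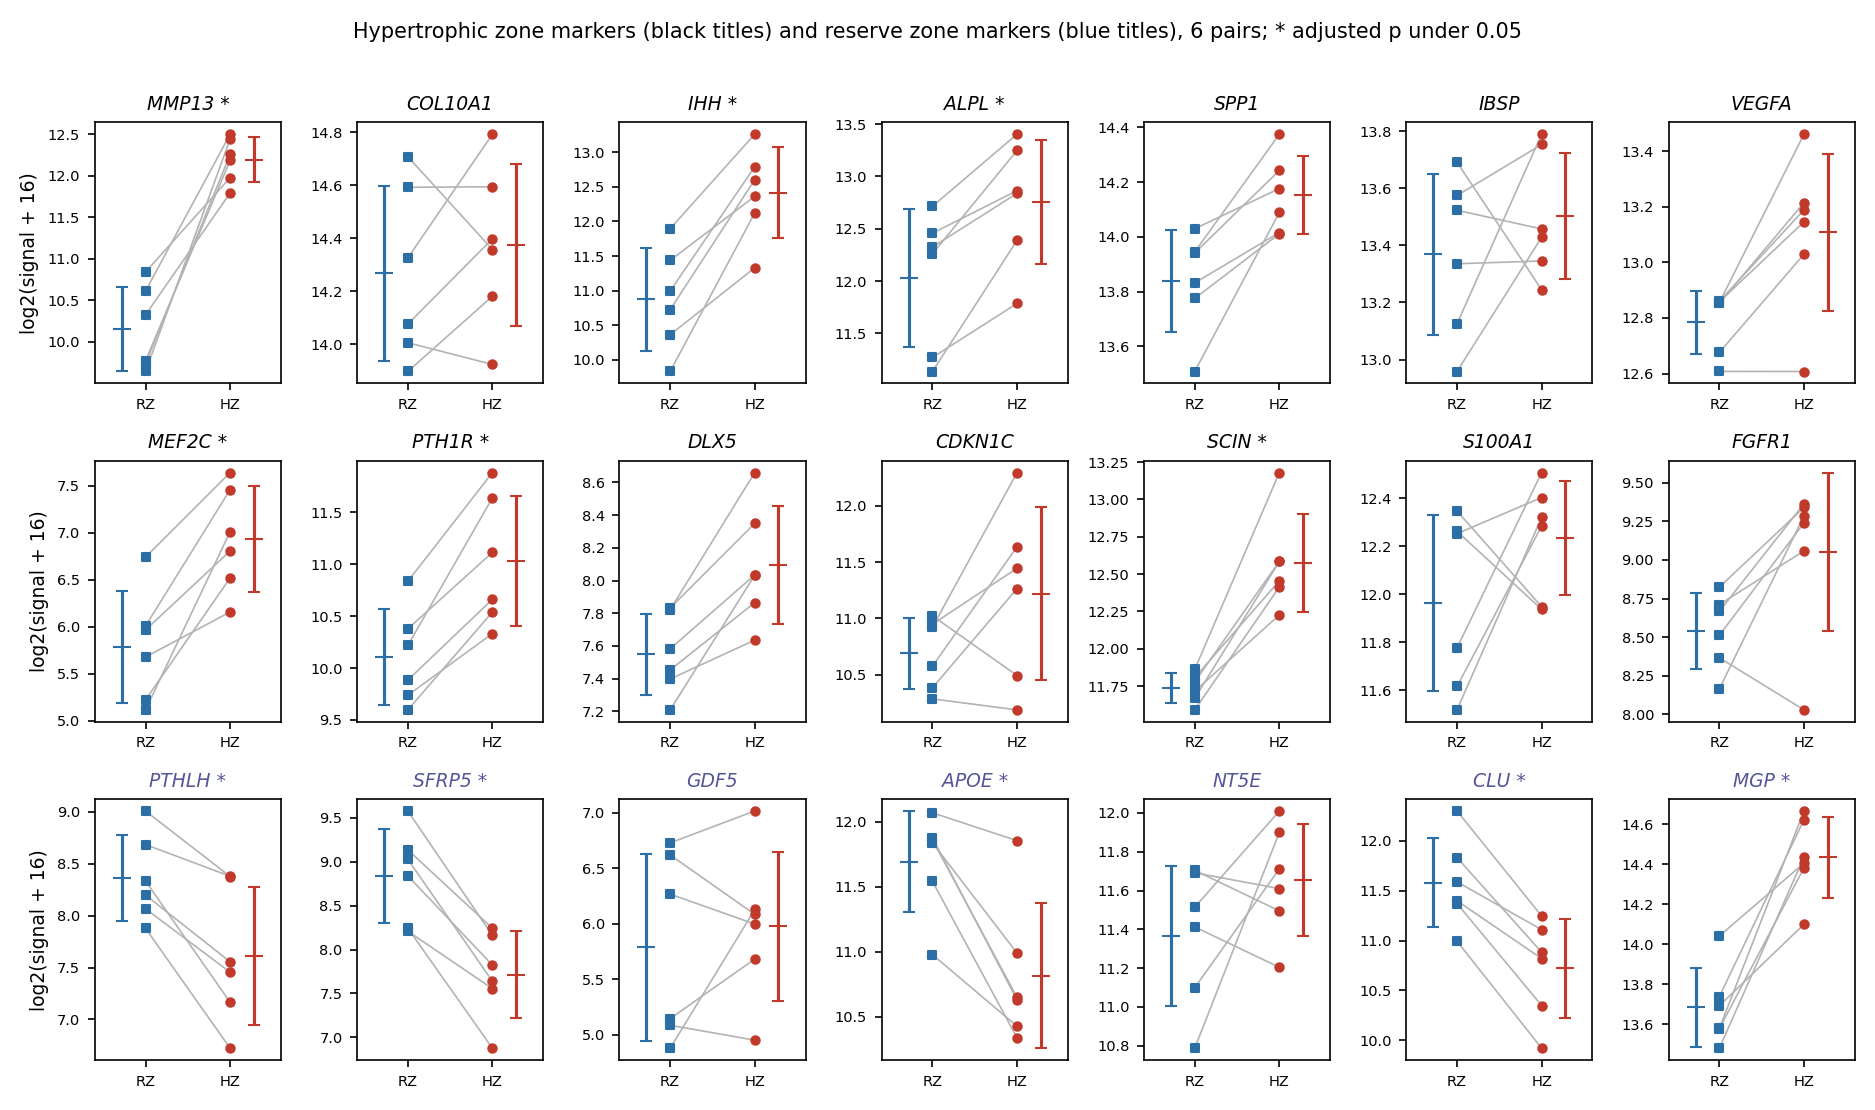
Log2(signal + 16) on the vertical axis of each panel for the measured hypertrophic zone markers (black titles) and reserve zone markers (blue titles), with blue squares for RZ, red circles for HZ, lines joining pairs, and the mean with its SD beside each zone. MMP13 and IHH rise in all 6 pairs and SFRP5 falls in all 6, while the lines of COL10A1 and IBSP go both ways.

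Few structural cartilage genes passed. Of 24 measured cartilage matrix genes, MGP rose and MATN1 fell (-0.84 ± 0.20, SE), also when adjusted over the list alone, and 22 did not pass (median -0.01, camera adjusted p = 0.667). Several of these were read from probe sets near the top of the range, where a difference can be missed. The bright probe sets of COMP and COL27A1 gave -0.04 and -0.08 and dimmer ones -0.66 ± 0.57 and -0.54 ± 0.16, which did not pass either (adjusted p = 0.561 and 0.0828). For COL11A1 the brightest gave 0.17, while a dimmer one rose by 0.76 ± 0.15 (adjusted p = 0.0189). None of 5 chondrocyte regulators passed (median -0.03, adjusted p = 0.630), but the ubiquitin ligase WWP2, at -0.44, passed as lower when adjusted over the list alone. Of 21 matrix proteases and inhibitors, MMP13, TIMP3 and CTSK rose and MMP2, ADAMTS4 and HTRA1 fell, with 15 not passing (5 and 4 adjusted over the list alone; median 0.02, camera adjusted p = 0.762). CTSK, cathepsin K, is a collagen-degrading enzyme that osteoclasts also make, and it rose by 1.46 ± 0.21 (0.85 in pairs 1 and 2, 1.76 in pairs 3 to 6). Among 15 mineralisation genes, ALPL, MGP and the mineral-binding protein DMP1 (1.34 ± 0.33, but -0.46 in pair 2) rose, the pyrophosphate transporter ANKH fell by 0.80 ± 0.13, and 11 did not pass, with the same counts adjusted over the list alone (median 0.07, adjusted p = 0.424). With a pair left out, DMP1 gave 1.12 to 1.70 and passed in 1 of the 6 fits, that without pair 2 (adjusted p = 0.00803, and up to 0.119 in the others).

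Genes that build glycosaminoglycans and process collagen went both ways. Of 18 glycosaminoglycan synthesis genes, EXT1 and HAS2 rose, and CHPF, PAPSS1, UGDH, UST and DSE fell, with 11 not passing (5 and 5 adjusted over the list alone; median -0.07, camera adjusted p = 0.735). HAS2, which makes hyaluronan, rose by 1.66 ± 0.22 (SE), although its other probe sets gave 0.28 to 0.55. CHPF, which lengthens chondroitin chains, fell by 0.97 ± 0.14, the uronyl sulphotransferase UST by 0.88 and DSE, which makes dermatan sulphate, by 0.82. In the 21 collagen processing genes, LOX, LOXL4 and P3H2 rose and P4HA3, SERPINH1 and P3H1 fell, with 15 not passing (3 and 7 adjusted over the list alone). The collagen chaperone SERPINH1 fell by 1.11 ± 0.14, the prolyl hydroxylase P4HA3 fell by 0.93 and its relative P3H2 rose by 0.93. That list had a median of -0.34 and did not pass (adjusted p = 0.0616).

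Several receptors and mediators of growth plate signalling differed. In the hedgehog and PTHrP pathway, IHH and PTH1R rose and PTHLH fell among 8 measured genes, also when adjusted over the list alone; its median (-0.13) and mean (0.12) differed in sign, and the test pointed up (camera adjusted p = 0.762). Of 19 WNT pathway genes, FRZB, TCF7L2 and RSPO3 rose and FZD1, SFRP5 and TCF7 fell (5 and 4 adjusted over the list alone). RSPO3, which strengthens WNT signals, rose by 1.53 ± 0.16 (SE), the transcription factor TCF7L2 rose by 1.23, and the receptor FZD1 fell by 0.90; the list's median was -0.16, its mean 0.04 and its test pointed down (adjusted p = 0.585). In the BMP pathway, the receptor ACVR1 (-0.92 ± 0.18) and the target gene ID3 (-0.96 ± 0.17) fell and 13 of 15 did not pass (BMP7 rising and 4 falling adjusted over the list alone), with a median of 0.01, a mean of -0.11 and a test pointing down (adjusted p = 0.644). Of 14 TGF-beta pathway genes, SMAD3 rose by 1.41 ± 0.19, though its other probe set gave 0.15, and TGFB1 (-0.71) and TGFBI (-1.18) fell, with 11 not passing (1 and 4 adjusted over the list alone; median -0.05, adjusted p = 0.492).

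FGF1 and SPRY2, an inhibitor that FGF signals induce, rose by 1.06 ± 0.18 and 0.83 ± 0.18 (SE) among 10 FGF pathway genes, also when adjusted over the list alone. FGF1 had 12 probe sets, and the others ran from -0.40 to 0.54. That list had a median of -0.11, a mean of 0.17 and a test pointing up (camera adjusted p = 0.492). IGFBP6, which binds IGF2, rose by 0.95 ± 0.20 as the 1 gene of 16 in the IGF and growth hormone pathway to pass, also when adjusted over the list alone (median 0.12, adjusted p = 0.644). The hormone nuclear receptors rose as a list of 10 genes, with a median of 0.21 (camera adjusted p = 0.0394; adjusted p = 0.489 with an estimated correlation). RARA, a retinoic acid receptor, rose by 0.82 ± 0.16, and RXRA and THRA passed with it when adjusted over the list alone. RXRA, the shared partner of these receptors, gave 0.61 ± 0.16 (adjusted p = 0.0582) and the thyroid hormone receptor THRA 0.60 ± 0.17 (adjusted p = 0.0682). The other RARA probe set gave 0.05, and the list's median was 0.36 in pairs 1 and 2 and 0.17 in pairs 3 to 6. Without pair 1, 2, 4 or 5 this list no longer passed (adjusted p = 0.0574, 0.0600, 0.0511 and 0.0573).

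As lists, genes of cell division were lower in HZ by camera at the preset correlation, but not by fry (adjusted p = 0.0956 for mitosis and for S phase), and few passed singly. The mitosis list of 18 genes fell with a median of -0.54 (camera adjusted p = 0.00089; adjusted p = 0.768 with an estimated correlation), at -0.65 in pairs 1 and 2 and -0.35 in pairs 3 to 6 (0.09 in pair 3). The spindle checkpoint kinase BUB1B fell by 0.82 ± 0.19 (SE) as the 1 gene to pass, and 7 fell when adjusted over the list alone. CCNB1, a cyclin of mitosis, stood at -0.95 ± 0.26 (adjusted p = 0.0652) and CDC20 at -0.54 ± 0.14 (adjusted p = 0.0573). The S phase list of 22 genes fell with a median of -0.23 (adjusted p = 0.0270; adjusted p = 0.768 with an estimated correlation), at -0.20 in pairs 1 and 2 and -0.27 in pairs 3 to 6 (0.03 in pair 3). In it UHRF1, which maintains DNA methylation, fell by 1.48 ± 0.27 and the replication helicase subunit MCM3 by 0.74 ± 0.18, also when adjusted over the list alone. Without pair 5 the S phase list did not pass (adjusted p = 0.0814), nor without pair 2 (adjusted p = 0.05585).

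Glycolysis fell as a list of 17 genes, with a median of -0.13 (camera adjusted p = 0.0119; adjusted p = 0.768 with an estimated correlation), at -0.30 in pairs 1 and 2 and -0.22 in pairs 3 to 6. HK1, PFKP, PGAM1 and PKM fell, also when adjusted over the list alone, and 13 genes did not pass. PFKP, a phosphofructokinase, fell by 1.36 ± 0.15 (SE), HK1, the first enzyme of the pathway, by 0.85, and the pyruvate kinase PKM by 0.77. In contrast, ADM, BNIP3L, EGLN1, LOX and EPAS1 rose among 21 hypoxia response genes and 0 fell (5 and 1 adjusted over the list alone). EPAS1, which encodes HIF-2 alpha, rose by 1.68 ± 0.17 and the oxygen sensor EGLN1 by 1.08 ± 0.15. The hypoxia list had a median of -0.08, a mean of 0.28 and a test pointing up that did not pass (adjusted p = 0.424). None of 39 oxidative phosphorylation genes passed, nor when adjusted over the list alone (median 0.12, adjusted p = 0.0551). LSS, an enzyme of cholesterol synthesis, fell by 1.20 ± 0.24 as the 1 gene of 15 in that list, also when adjusted over the list alone, with its other probe sets at -0.87 and 0.51 (median -0.10, adjusted p = 0.373). Of 17 ion and water transport genes, the sodium pump subunit ATP1B1 (0.72 ± 0.17), carbonic anhydrase CA2 (0.78 ± 0.14) and the potassium channel KCNK5 (1.12 ± 0.19) rose. In that list 3 rose and 1 fell when adjusted over the list alone, the median was -0.06, the mean 0.03 and the test pointed up (adjusted p = 0.762).

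All 20 measured genes of the unfolded protein response had a difference below 0, and the list fell with a median of -0.33 (camera adjusted p = 0.000806; adjusted p = 0.768 with an estimated correlation and 0.0956 by fry). The median was 0.24 in pair 1 and -0.53 in pair 2, and ran from -0.21 to -0.61 in pairs 3 to 6. TRIB3, a pseudokinase induced by this response, fell by 0.92 ± 0.15 (SE) as the 1 gene to pass, with 2 falling when adjusted over the list alone, and the chaperone HYOU1 stood at -0.77 ± 0.21 (adjusted p = 0.0635). SEC61A1, a channel of the endoplasmic reticulum, fell by 0.64 ± 0.13 among 26 secretory pathway genes, also when adjusted over the list alone (median -0.17, adjusted p = 0.119). The death receptor FAS rose by 1.17 ± 0.18 among 14 apoptosis genes, also when adjusted over the list alone (median 0.18, adjusted p = 0.160). Of 25 immediate early and heat shock genes, GADD45A (1.28 ± 0.18) and IER2 (0.72 ± 0.16) rose, also when adjusted over the list alone (median 0.09, adjusted p = 0.155). No gene passed among 28 ribosomal proteins (median 0.07, adjusted p = 0.424, with the direction of the test turned after quantile normalization) or 21 lysosome and autophagy genes (median -0.04, adjusted p = 0.950), nor when adjusted over the list alone.

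Inflammatory response genes fell as a list of 21, with a median of -0.48 (camera adjusted p = 0.00843, adjusted p = 0.489 with an estimated correlation and 0.0558 by fry). The median was -0.64 in pairs 1 and 2 and -0.42 in pairs 3 to 6. IL6, CCL20, TNFAIP6, LIF and SAA3 fell, PTGS2 rose and 15 did not pass (10 falling and 1 rising adjusted over the list alone). The chemokine CCL20 fell by 1.03 ± 0.21 (SE) and the acute phase protein SAA3 by 0.90 ± 0.18. PTGS2, which makes prostaglandins, rose by 0.97 ± 0.18. Leukocyte genes changed beside them. Of 16 measured, CSF1R, AIF1, C1QA, C1QB and C1QC rose and PTPRC fell (6 and 3 adjusted over the list alone; median 0.05, camera adjusted p = 0.345), with list medians of -0.71 in pairs 1 and 2 and 0.37 in pairs 3 to 6. AIF1, found in macrophages, rose by 1.99 ± 0.18 and the complement genes C1QA, C1QC and C1QB by 1.95, 1.80 and 1.64, with mean signals of 33.2 to 355 for these 4 genes over both zones. The monocyte receptor CD14 stood at -0.81 ± 0.26 (adjusted p = 0.103), while its second probe set fell by 1.02 (adjusted p = 0.0254), and the macrophage protein CD68 stood at 0.14 ± 0.14 (adjusted p = 0.643).

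Markers of other cell types in bone and its surroundings also differed. The osteoclast list of 7 genes rose with a median of 0.97 (camera adjusted p = 0.00281; adjusted p = 0.489 with an estimated correlation), at 0.55 in pairs 1 and 2 and 1.42 in pairs 3 to 6. CTSK, the integrin ITGB3 (1.46 ± 0.19, SE) and the acid phosphatase ACP5 (1.21 ± 0.29) rose, with 4 rising when adjusted over the list alone. The other probe sets of ITGB3 gave 0.69 to 0.95 and those of ACP5 0.49 and 0.79, and none of these passed. The fibroblast and perichondrium list of 14 genes fell with a median of -0.50 (adjusted p = 0.00281; adjusted p = 0.489 with an estimated correlation), at -0.78 in pairs 1 and 2 and -0.31 in pairs 3 to 6. PDGFRA, TNC, FBN1, ELN and FAP fell and 9 did not pass, with 7 falling when adjusted over the list alone. FBN1 fell by 1.46 ± 0.18, the matrix protein tenascin (TNC) by 1.41, the surface protease FAP by 1.20 and the growth factor receptor PDGFRA by 1.01. Other, dimmer probe sets gave 0.07 for TNC and 0.09 to 0.14 for PDGFRA. Fibrillar collagen COL1A2 stood at -1.12 ± 0.29 (adjusted p = 0.0515), COL1A1 at -1.05 ± 0.34 (adjusted p = 0.105; -2.23 in pairs 1 and 2 and -0.46 in pairs 3 to 6) and COL3A1 at -0.14 ± 0.19.

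DMP1 was the 1 gene of 8 to pass among osteoblast and osteocyte markers (1 rising and 3 falling adjusted over the list alone; median -0.24, camera adjusted p = 0.523), and SPARC, abundant in bone, stood at 0.12 ± 0.16 (SE). The endothelial adhesion protein PECAM1 fell by 1.06 ± 0.23 as the 1 gene of 13 in its list, also when adjusted over the list alone, and the endothelial transcription factor ERG stood at -0.19 (median -0.02, adjusted p = 0.755). Among 10 mural cell genes, ACTA2 (0.84 ± 0.17) and the muscle filament protein DES (1.81 ± 0.26) rose, with 2 rising and 2 falling adjusted over the list alone, and TAGLN stood at -0.77 (median 0.05, adjusted p = 0.701). By its brightest probe set, no gene passed among 8 erythroid genes (median 0.09, adjusted p = 0.772), 7 adipocyte genes (median 0.19, adjusted p = 0.536) or 9 skeletal muscle genes (median 0.37, adjusted p = 0.398). Adjusted over the list alone, the adipocyte gene FABP4 rose and 0 erythroid or muscle genes passed.

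**Figure D4:**
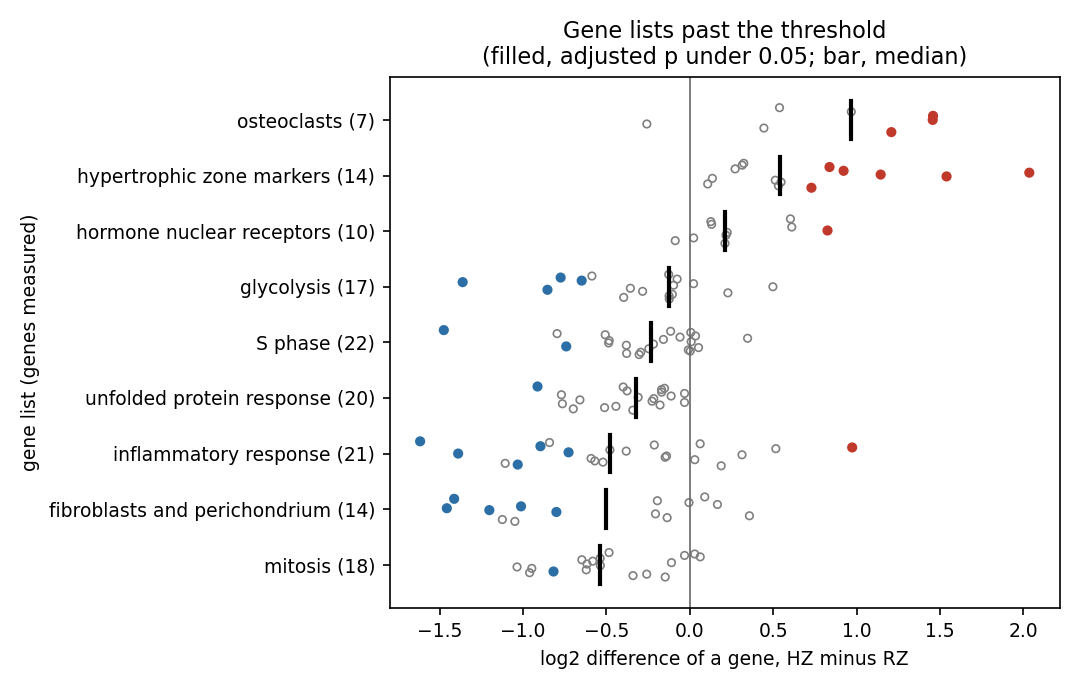
Log2 difference, HZ minus RZ, on the horizontal axis for each measured gene of the 9 lists past the threshold, 1 list per line with its number of genes, with filled circles for genes with an adjusted p under 0.05 (red higher, blue lower), open circles for the rest and a black bar at the median. Osteoclast and hypertrophic zone genes lie mostly to the right, and mitosis and fibroblast genes mostly to the left.

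Over the 38 lists, camera with a preset correlation of 0.01 passed 3 as higher and 6 as lower, and 0 passed with the correlation estimated, where 3 lists had an unadjusted p under 0.05. By fry, which tests each list on its own, 5 passed, namely hypertrophic zone markers, hormone nuclear receptors, osteoclasts, glycolysis, and fibroblasts and perichondrium. Of the 121 genes named here with alternatives, 97 passed, and 60 of these did so with each pair left out in turn. The losses were 25 genes without pair 1, 16 without pair 2, 5 without pair 3, 29 without pair 4, 32 without pair 5 and 22 without pair 6. In 1 of the 6 such fits passed ACTA2, ALPL, ATP1B1, DMP1, MATN1, MCM3, PECAM1, PGAM1, PKM, PTHLH and SEC61A1, with adjusted p up to 0.123 and log2 differences of at least 0.816 times those given. In 2 passed ACP5, ACVR1, BUB1B, CATHL1, CCL20, CXCR4, DPEP1, IER2, IGFBP6, SPRY2 and TGFB1 (up to 0.114, at least 0.764 times). In 3 passed APOE, DSE, MGP, MMP2, PDGFRA and SAA3 (up to 0.0795), and in 4 C1QA, NKG7 and RARA (up to 0.0666). In 5 passed CA2, FAP, LSS, P4HA3, PTGS2 and UHRF1 (up to 0.0553).

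Genes counted by their brightest probe set were not always alike in the others. Of 33 genes among the 97 with more than 1 probe set, 22 had another that did not pass. In the lists, 13 genes counted as not passing did so by another probe set. These were higher for AHSG (1.13 and 1.41), BMP7 (0.78), COL11A1 (0.76), IBSP (2.20) and MYH1 (0.80), and lower for BIRC3 (-0.71), BMPR1A (-0.88), CD14 (-1.02), DKK3 (-1.04), GHR (-0.65), MMP16 (-1.07), NOS2 (-1.38) and TIMP2 (-0.82 and -0.93). The other COL1A1 probe set, near the floor, gave 0.07.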

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

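The splits of the arrays were planned, and the tests of bright probe sets, leukocyte genes and NT5DC1 below were chosen only after the results were seen, with the comparisons for bright probe sets and the gene sets and conditions for leukocytes changed after first versions had been run. A test of mitosis genes by batch was dropped.

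Among 248 groups of 6 arrays, 1 per zone for each of the named genes with alternatives and for the RNA quality ratios, 10 had an array far from the others, where chance gives about 1 in 20, or 12.4. The gap between that array and its neighbour took up 0.677 of the group's range for NCALD on HZ-2 (lowest, log2 signal 10.34 against 11.44 ± 0.18 on the other 5), 0.771 for FGFR1, 0.778 for RSPO3 and 0.738 for PTGS2, all lowest on HZ-2. It was 0.720 for DPEP1 on HZ-5 (highest), 0.740 for TNFAIP6 on HZ-1 (lowest), 0.695 for DSE on RZ-1 (lowest), 0.665 for SERPINH1 on RZ-6 (highest), 0.645 for ERG on RZ-6 (highest) and 0.627 for CD68 on RZ-4 (lowest).

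Chance is unlikely to explain the number of probe sets that passed. It is not excluded, since the smallest shares these splits could give were 1 of 32 and 1 of 100. With the pair as a block the real split gave 1494 and the highest of the other 31 ways of swapping zones within pairs gave 0, so that 1 of the 32 reached it. Without the block the real split gave 831 and the highest of 99 other splits 201, again 1 of 100. The split with 201 had all 4 arrays of pairs 1 and 2 in the same group, and the 4 such splits had a median of 0.5.

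The brightest probe sets showed little difference between the zones, COL10A1 among them. Signals near the top of the range may no longer follow the RNA level. Within a pair the 100 brightest differed from their shared median by 0.115, against 0.293 in a band of 500 dimmer ones, a ratio of 0.3925, but a smaller difference in the RNA itself would give the same. In genes with a probe set above 8000 and a dimmer one, the dimmer one differed more in 25 of 32, against 106 of 180 genes at 0.25 times these levels, an odds ratio of 2.483 (95% interval 0.979 to 7.17, Fisher's exact p = 0.0480), so that these cannot be told apart with 32 genes. IBSP was not among the 32, since the mean over all arrays lay above 8000 for both its probe sets. The one brighter over all arrays gave 0.14. The other, with a mean signal of 2981 in RZ and 13565 in HZ, gave 2.20 (limma adjusted p = 0.00125).

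Leukocyte genes went both ways, with 8 of 22 macrophage genes higher in HZ and 2 of 21 lymphocyte genes and 1 of 14 granulocyte genes lower. A larger share of leukocytes of every kind in HZ would raise lymphocyte and granulocyte genes too. Of the 15 above the arrays' median signal, without CATHL1 and NKG7, already seen to fall, 14 were below 0, with a mean of -0.5161. This cannot decide the question, since that mean had an SD of 0.677 over the pairs and was above 0 in pairs 4 and 5 (exact sign-flip p = 0.1875). Of the 15, 10 were granulocyte genes. The common leukocyte gene PTPRC fell by 1.72 (adjusted p = 0.0463) at 1 probe set, while its other 2 gave -0.24 and 0.19. Macrophages in the HZ fraction may add transcripts. A set of 11 macrophage genes outside the fixed lists, with SLCO2B1 left out since its rise (1.95) had already been seen, shifted upward (fry p = 0.002347; exact sign-flip p = 0.03125, the smallest possible). Of these 11, 9 were above 0 and 2 passed, MERTK (1.89) and CTSS (1.36). The others ran from -0.36 (LYVE1) to 0.65 (VSIG4), so the shift of the mean rests largely on those 2. The set was put together after the results were seen, so its fry and sign-flip p-values cannot decide whether macrophages were present. The median of the 11 was 0.04 in pair 2 and -0.35 in pair 6. CD14 (-0.81), LAPTM5 (-0.03) and FCER1G (-0.05), which macrophages express strongly, did not rise. Lymphocytes and granulocytes in the RZ fraction stay open, with fry p = 0.05095 over 35 genes (exact sign-flip p = 0.03125). These p-values cannot decide it, since the set holds CATHL1 and NKG7, whose fall had been seen before the set was made. Lymphocyte genes alone, with NKG7, gave an exact sign-flip p of 0.03125. Granulocyte genes alone, with CATHL1, gave 0.21875, and their mean was above 0 in 2 of 6 pairs. No sort or gate beyond density would have removed such cells, and a difference of the zones in life is another open, untested explanation.

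NT5DC1 rose most, and COL10A1 lies within it. Transcripts of COL10A1 may bind that probe set, but COL10A1 differed by 0.1071 near the top of the range, and with 1 probe set for each gene this cannot be told apart from a rise of NT5DC1 itself. A zone difference in NT5DC1 was not tested in another way.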

How the results depend on the processing

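The deposited ratio, each batch alone, the arrays without pairs 3 and 4, and lists without probe sets above a signal of 8000 were chosen after the data were seen. Counts depended on the number of pairs and on the handling of dim signals. For the 97 named genes that passed, the direction held under all 20 settings run for single genes (85 genes) or all 19 of these that kept the probe set (12 genes). This was largely fixed by their choice, since the paired test favours genes with the same sign in all pairs. In such genes, leaving out pairs or changing the added constant cannot turn the direction. Over the planned settings with all pairs, 1069 of 1197 gene values and 270 of 298 list values kept their direction and side of the threshold. With a pair left out it was 593 of 726 and 212 of 228, and under the settings chosen later 212 of 484 (265 no longer passing) and 163 of 189. Of the 97 genes, 54 passed with the deposited ratio, 45 in pairs 3 to 6, 24 without pairs 3 and 4, 0 by limma in pairs 1 and 2, 63 without the block, 61 with 1 added and 85 with the block as a random effect. Below, higher and lower are counts of probe sets in HZ, 782 and 712 as reported, with 364 and 249 of 2-fold or more. Where no value below is given, a count stayed within 1.5 times of these, and the cause was not tested.

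Without the pairing (no block), 505 were higher and 326 lower, 155 of these 2-fold or more; 796 of the 831 were among the 1494 with the block, all with the same sign. Of the lists, hormone nuclear receptors no longer passed (adjusted p = 0.0593) and oxidative phosphorylation did (0.0353), and lysosome and autophagy turned direction (0.954). An added constant of 1 gave 368 and 215 (154 lower 2-fold or more), and 64 gave 1120 lower, with 212 and 123 of 2-fold or more. Without the dimmest 50% of probe sets 1374 were lower. A variance trend with robust moderation gave 1167 lower, and a paired test without moderation 194 and 135 (109 and 29 of 2-fold or more). The deposited ratio gave 315 and 163, with 123 lower 2-fold or more.

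Pairs 3 to 6 alone gave 258 and 78, all 78 of 2-fold or more, and 5 lists higher. Pairs 1 and 2 alone gave 0 and 0 by limma, 0 and 0 of 2-fold or more (2931 probe sets at an unadjusted p under 0.05), and 3 lists lower, with S phase (adjusted p = 0.176), glycolysis (0.176), unfolded protein response (0.565) and osteoclasts (0.161) not passing. Without pairs 3 and 4 there were 91 and 48, all of 2-fold or more. Fewer pairs leave fewer degrees of freedom. With each pair left out in turn, higher ran from 334 (without pair 5) to 650, lower from 223 (without pair 5) to 895 (without pair 3), higher by 2-fold or more from 259 to 418, lower by 2-fold or more from 156 (without pair 1; 162 without pair 4 and 162 without pair 5) to 294, lists higher from 2 to 4 and lists lower from 5 to 8. The count of higher was over 1.5 times smaller also without pair 1 (383), 4 (384) and 6 (466), and that of lower without pair 1 (242), 2 (406), 4 (248) and 6 (348). With an estimated correlation 0 lists were higher and 0 lower, and fry gave 2 lower. Hormone nuclear receptors also did not pass without the dimmest 25% (adjusted p = 0.0511), with the mean of a gene's probe sets (0.0653), in pairs 3 to 6 (0.118) and without pairs 3 and 4 (0.0565), nor S phase without the dimmest 25% (0.0514). Oxidative phosphorylation passed after quantile normalization (0.00545), without the dimmest 50% (0.0426), under a signal of 8000 (0.0477) and in pairs 3 to 6 (0.0147), and collagen processing after quantile normalization (0.0240) and under a signal of 8000 (0.0295). In pairs 3 to 6 leukocytes (0.0154) and immediate early and heat shock (0.0262) passed and inflammatory response (0.0751) did not. Secretory pathway passed without pairs 3 and 4 (0.0226). With a single pair left out, oxidative phosphorylation passed without pair 1 (0.0438), 2 (0.0222), 4 (0.0498) or 6 (0.0169), immediate early and heat shock without pair 1 (0.0438), and secretory pathway (0.00511) and collagen processing (0.0361) without pair 3. Hormone nuclear receptors did not pass without pair 1 (0.0574), 2 (0.0600), 4 (0.0511) or 5 (0.0573), nor S phase without pair 2 (0.05585) or 5 (0.0814).

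Directions turned only in results that had not passed, which choosing genes by the threshold favours. After quantile normalization these were COL10A1 (log2 difference -0.046) and the lists of ribosomal proteins (adjusted p = 0.643) and lysosome and autophagy (0.701). Without the dimmest 25% it was erythroid cells (0.795), and without the dimmest 50%, lysosome and autophagy (0.730) and leukocytes (0.695). With the mean of a gene's probe sets it was osteoblasts and osteocytes (0.908), and under a signal of 8000, matrix proteases (0.815) and ion and water transport (0.990). In pairs 3 to 6 these were COL3A1 (0.011), hedgehog and PTHrP (0.966), lysosome and autophagy (0.932) and erythroid cells (0.804). In pairs 1 and 2 they were IBSP (-0.028), CDKN1C (-0.016), S100A1 (-0.087), GDF5 (-0.40), ERG (0.00996), cartilage matrix (0.552), WNT (0.989), hypoxia response (0.975), ribosomal proteins (0.971), immediate early and heat shock (0.975) and leukocytes (0.347). Without pairs 3 and 4 they were IBSP (-0.0082), chondrocyte regulators (0.775) and lysosome and autophagy (0.953). Among the settings with a pair left out, lysosome and autophagy turned without pair 1 (0.970) and pair 4 (0.787; range 0.787 to 0.999), erythroid cells without pair 1 (0.961; range 0.717 to 0.961), COL3A1 without pair 2 (0.047; range -0.20 to 0.047) and GDF5 without pair 5 (-0.023; range -0.023 to 0.33). The cause was not tested. Signal near the floor limits the dim probe sets, and the added constant shrinks their differences.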

Other observations

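The gene sets in this part were put together after the results were seen and hold genes whose change prompted them, so no p is given for a set. Cells that take up other cells or debris use MERTK, a receptor for dying cells, and its signal went from 469 in RZ to 1879 in HZ, a log2 difference of 1.89 ± 0.16 (SE, adjusted p = 0.000708, higher in 6 of 6 pairs). Among 22 measured macrophage genes, AIF1, C1QA, C1QB, C1QC, CSF1R, CTSS, MERTK and SLCO2B1 rose and 0 fell by their brightest probe sets, with a median of 0.57. Of the 22, 10 are also on the fixed lists. CD14 stood at -0.81 (limma adjusted p = 0.103), and its second probe set fell by 1.02 (adjusted p = 0.0254). The transporter SLCO2B1 rose by 1.95 ± 0.25 and the protease CTSS by 1.36 ± 0.29. Medians by pair ran from 0.13 in pair 2 to 1.08 in pair 4.

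Among 21 lymphocyte genes, the T cell adhesion protein CD2 (-0.96 ± 0.23) and NKG7 fell and 0 rose, with a median of -0.36 that ran from -0.87 in pair 2 to -0.01 in pair 5. CCL5, the brightest, stood at -1.11 ± 0.34 (adjusted p = 0.0906). Of 14 granulocyte genes, CATHL1 fell and 0 rose (median -0.74). Their medians were -2.03 in pair 1, -1.37 in pair 2 and -1.08 in pair 6, against -0.04, 0.28 and 0.29 in pairs 3, 4 and 5.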
